A study of Rattus norvegicus with 6 samples.

How the data were processed

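RNA was measured in 6 samples of primary rat nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc, taken from male animals and used at passages 3 to 6, per the labels. Of these, 3 libraries came from cells held for 48 h in medium without fetal bovine serum and 3 from cells in medium with 10% serum. Per the labels' protocols, total RNA was depleted of ribosomal RNA with captured probes, fragmented by heat and reverse transcribed from random primers, so transcripts without a poly(A) tail could be read as well. The labels do not say that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

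The authors deposited 1 table per library with the same 17093 genes and 1 value per gene, rounded to 2 decimals. The file headers name no unit. The values are treated here as FPKM (fragments scaled by transcript length and library total), because the deposited columns are not whole numbers and sum to different totals in each library. TPM over a wider gene set cannot be excluded and would differ only by a factor per library, which the alternatives with another scaling address. Per the submitters' processing notes, bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma were used, and the genome build is named as mm10, a mouse build. The gene identifiers in the files are rat identifiers, of which 15927 (93.2%) matched a rat gene in a table of the GRCr8 assembly. The build and annotation behind the values are therefore open, no coordinates are given, and the table served for gene names only. Whether fragments were assigned by strand, and how fragments matching several genes were divided, is not given in the sources used here. The step from reads to values could thus move reads between near-identical genes, and such genes are called uncertain. Some symbols had been turned into dates by a spreadsheet program, and 5 symbols stood on more than 1 row, which were told apart by their gene ID.

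No counts accompany the values, so the depth of each library is unknown and no counting interval is given. Low values of olfactory receptor genes were also read, kept only inside a narrow window fixed in advance. Their medians were 0.07 to 0.08 in each library, but the window largely sets such a median, so no step was detected. They came from 4 to 10 genes in values rounded to 2 decimals, which is too coarse to compare depths. The values of a library summed to between 447788 and 473452 in serum-starved cells and between 522165 and 530095 in control cells. No pair of libraries was close to identical: among genes with a value of at least 5 in both libraries, at most 0.26% of values were equal within a pair. Separately, 409 genes were listed at 0 in every library.

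Values were analysed as log2(value + 1), so fold changes on this scale understate the change of low genes. Genes with a value of at least 1 in at least 3 of the 6 libraries were tested, which kept 11493 genes and left out 5600. Serum-starved and control libraries were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, treatment as the only term and 4 residual degrees of freedom per gene. A gene was said to rise or fall at a Benjamini-Hochberg adjusted p of at most 0.05. With 3 libraries against 3, an exact permutation test of a single gene cannot give a two-sided p below 0.1, which is why the model across genes was used. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

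Before the data were examined, 39 gene lists holding 677 symbols were fixed, covering cell cycle, signalling, matrix, metabolism, stress, immune genes, RNA quality and markers of other cells that a disc culture could hold. Of these symbols, 618 were matched. The lists of mitochondrially encoded genes and of abundant non-coding RNAs, meant to describe RNA quality, could not be analysed, because no symbol on them was matched. Lists with at least 5 tested members were compared with all other tested genes by camera, with a preset inter-gene correlation of 0.01 and adjustment over 30 lists. The same test with a correlation estimated for each list, and fry, which asks whether a list's genes move one way on balance, were run beside it. Genes named in the text followed a rule fixed at the same time: the 10 largest rises and 10 largest falls among changed genes with non-overlapping groups, a mean of at least 5 in the higher group and a settled symbol; up to 4 changed members with the largest change in each list; and the 5 most abundant genes that rose and that fell. Outside this rule, and after their values were seen, Hprt1, Rpl10 and the near-copies Anlnl1, Aspnl1 and LOC100362149 were named in the results, as were genes listed at the start of the closing observations, and some genes that the rule names are not reported here.

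The test was checked on simulated data with the means and spread of these libraries and independent noise. Known factors changed 200 genes, and 11318 genes reached the filter and were tested. In this simulation the procedure called 72% of genes changed 1.5-fold, 78% changed 2-fold and 98% changed 4-fold. It gave 0 wrong signs, and 5.78% of its calls were unchanged genes. In the real comparison 61.1% of tested genes were called, a far larger share, so these rates do not carry over to it. The alternatives tried were the replicate number as a block, pseudocounts of 0.1 and 0.5, no filter, a filter at 5, median-ratio scaling, quantile normalization, limma without the trend, library quality weights, and leaving out each library in turn.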

Results

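Gene expression was profiled by RNA sequencing in primary rat nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc. Serum starvation, the withdrawal of fetal bovine serum and its growth factors and lipids, was applied for 48 h in 3 libraries. The other 3 libraries came from control cells kept in 10% serum. Each library gave a value for the same 17093 genes, treated as FPKM, and between 11153 and 11254 genes per library had a value of at least 1. Values summed to 459262 ± 13046 (SD, n = 3) in serum-starved and 524903 ± 4498 (SD, n = 3) in control libraries. The depth in reads is unknown. Values below are the deposited ones, as mean ± SD over 3 libraries, and log2 fold changes are serum-starved minus control on the log2(value + 1) scale with their standard error. Folds of single genes are ratios of the mean deposited values, whereas counts of genes changed at least 2-fold use the log2(value + 1) scale.

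The design asks which transcripts differ between cells without serum and cells with it. All tested genes of the mitosis and DNA replication lists fell in serum-starved cells, as did most of those on the glycolysis and hypoxia, cholesterol synthesis and immediate early lists, while most tested complement genes and 14 of 25 autophagy and lysosome genes rose. Rrm2 (gene ID 362720), the small subunit of ribonucleotide reductase, fell from 245 ± 38.4 to 1.78 ± 0.491 (n = 3 each), 137-fold lower. Aspn (gene ID 306805), which encodes the small matrix proteoglycan asporin, rose from 0.370 ± 0.0173 to 120 ± 27.8 (n = 3 each), with a log2 fold change of 6.44 ± 0.157 (SE). Acan (gene ID 58968), which encodes aggrecan, the main large proteoglycan of the nucleus pulposus, fell from 77.5 ± 28.1 to 3.05 ± 0.333 (n = 3 each), 25.4-fold lower. In all, limma with Benjamini-Hochberg adjustment called 7024 of 11493 tested genes (61.1%), 3640 higher and 3384 lower in serum-starved cells.

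**Figure D1:**
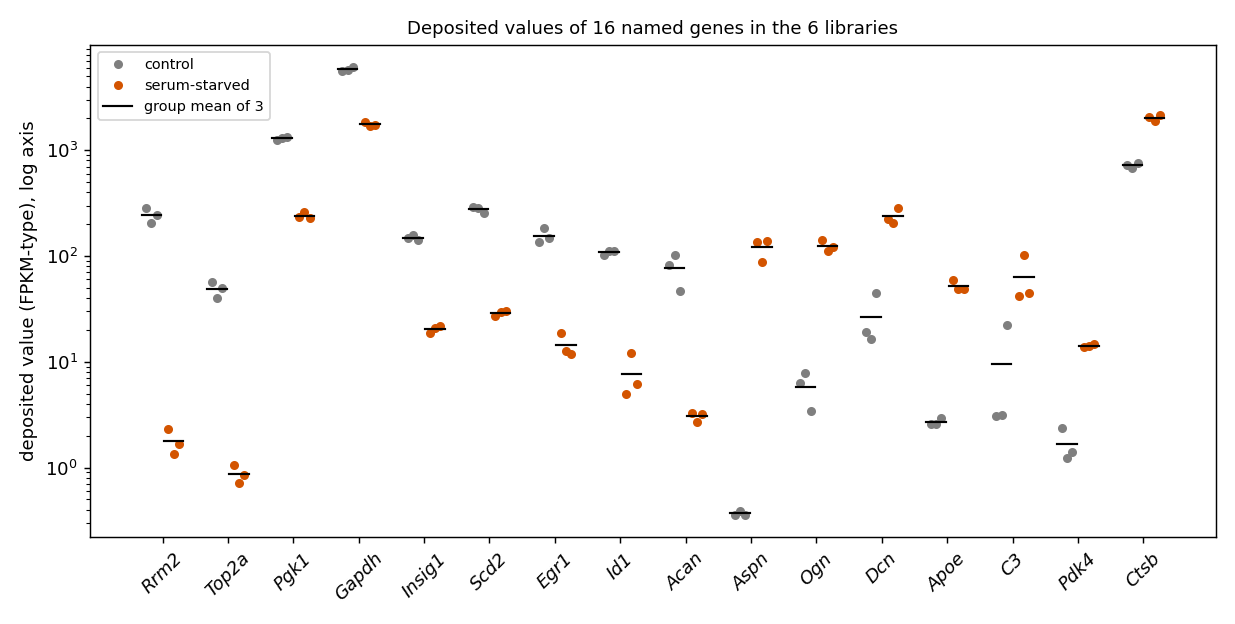
Deposited values (FPKM-type, log axis) of 16 named genes in each of the 3 control (grey) and 3 serum-starved (orange) libraries, with bars at the group means. Rrm2 lies at 207 to 284 in control and 1.34 to 2.31 in serum-starved libraries, and C3 in control replicate 3 lies at 22.1 against 3.10 and 3.17 in the other controls.

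At a change of at least 2-fold, 479 genes rose and 825 fell. The largest rises under the naming rule, after Aspn, were Angptl4, Nov, Cpz, Ogn, Hist2h2aa3, Tnfrsf11b, Wfdc18, Apoe and Car3. Angptl4 encodes an inhibitor of lipoprotein lipase and rose 29.3-fold, from 2.61 ± 2.32 to 76.5 ± 7.82, with 5.28 in control replicate 3 against 1.39 and 1.16 in the other controls. Nov, a secreted CCN-family protein, rose 25.4-fold to 314 ± 103, and Ogn, which encodes the proteoglycan osteoglycin, rose 21.5-fold to 125 ± 15.9. Tnfrsf11b, the decoy receptor osteoprotegerin, rose 25.6-fold to 38.4 ± 10.9, Cpz, a carboxypeptidase, rose 43.2-fold to 39.0 ± 9.23, and Apoe, a lipid-carrying apolipoprotein, rose 19.3-fold to 52.3 ± 6.26. Wfdc18 rose 12.8-fold, with 44.95 in control replicate 3 against 8.57 and 19.6 in the other controls. The histone gene Hist2h2aa3 was listed at 0 in all 3 control libraries and at 17.9, 18.5 and 9.59 in the serum-starved ones. Hprt1, a gene that every cell uses, named here after its values were seen, was also listed at 0 in 2 of those controls, so such zeros can be failed estimates. The largest falls after Rrm2 were Cdca3, Ube2c, Pttg1, Cdkn3, Anln, Pimreg, Top2a, Kif20a and Ccna2, between 41.6-fold (Cdkn3) and 125-fold (Pimreg) lower. Pimreg was near the floor in serum-starved libraries, at 0.51, 0.22 and 0.19, so its ratio is imprecise, and its log2 fold change was -4.92. Among these 20 genes, limma gave a highest Benjamini-Hochberg adjusted p of 0.000234 (Wfdc18).

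All 26 tested genes of the mitosis list fell, with a median log2 fold change of -3.94. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was 52.6-fold lower, Top2a (topoisomerase II alpha) 55.7-fold, Kif20a, a kinesin of cytokinesis, 43.4-fold and Anln 42.6-fold. The camera test gave a Benjamini-Hochberg adjusted p = 1.6e-18 for this list, and adjusted p = 0.274 with an estimated correlation. All 26 genes of the DNA replication list fell as well (median -1.95). Besides Rrm2, thymidine kinase Tk1 was 21.2-fold lower, the helicase subunit Mcm5 23.9-fold and Uhrf1, which recruits the maintenance DNA methyltransferase, 22.2-fold. The DNA replication list had a camera Benjamini-Hochberg adjusted p = 2.92e-15, and adjusted p = 0.274 with an estimated correlation.

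Of 16 CDK inhibitor and growth arrest genes, 9 rose, 5 fell and 2 did not pass the test. Gas1, a membrane protein first found in growth-arrested fibroblasts, rose 6.45-fold to 46.5 ± 2.09. Gas6 rose 3.65-fold, the cyclin G family gene Ccng2 3.03-fold and the transcription factor gene Foxo1 2.98-fold. A difference of this list from the other genes was not shown (camera, Benjamini-Hochberg adjusted p = 0.0935, in a range of 0.0544 to 0.131). The immediate early genes, which respond to growth factors within minutes, were mostly lower: 12 of 15 fell, 1 rose and 2 did not pass, with a median log2 fold change of -1.70. Fosl1 was 15.8-fold lower, Egr1 10.9-fold, Fos 7.83-fold and Dusp5, a phosphatase of ERK, 4.69-fold. The list had a camera Benjamini-Hochberg adjusted p = 4.64e-05, and adjusted p = 0.274 with an estimated correlation. Among 16 p53 target genes 8 rose, 5 fell and 3 did not pass, or 9 and 5 when adjusted over the list alone. Tp53inp1 rose 3.72-fold and Fas 1.84-fold, while Btg2 fell 1.99-fold and Bbc3, which encodes the cell-death protein PUMA, fell 1.88-fold (camera, Benjamini-Hochberg adjusted p = 0.37). The 21 apoptosis machinery genes split into 7 that rose, 7 that fell and 7 that did not pass. Bmf rose 3.00-fold and Xiap 1.63-fold, while Cycs fell 1.55-fold and Bcl2l1 1.499-fold. For this list the median and mean log2 fold changes were 0.02 and 0.04, while camera gave the direction as down. The median was -0.005 under median-ratio scaling, and a difference from the other genes was not shown (camera, Benjamini-Hochberg adjusted p = 0.873). The counts of list members without single libraries were added after seeing the data. Without serum-starved replicate 3, 3 apoptosis genes rose, 5 fell and 13 did not pass, and 4 rose without control replicate 2. Without serum-starved replicate 3, 3 p53 target genes fell, and 0 immediate early genes rose without that library or without control replicate 1.

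Of the 21 tested cholesterol synthesis genes, 20 fell, 0 rose and 1 did not pass, with a median log2 fold change of -1.07. Insig1, which encodes a sterol-regulated membrane protein, fell 7.31-fold, from 149 ± 9.24 to 20.4 ± 1.66. The enzyme gene Idi1 fell 3.70-fold. Camera gave a Benjamini-Hochberg adjusted p = 2.01e-09 for the list, and adjusted p = 0.205 with an estimated correlation. In the fatty acid synthesis list 11 of 13 genes fell, 1 rose and 1 did not pass (median -0.93). Scd2, a fatty acid desaturase, fell 9.56-fold, from 277 ± 18.3 to 28.9 ± 1.52, Fads1 fell 4.94-fold, Fads2 2.61-fold and Fasn, the fatty acid synthase, 2.73-fold. The camera Benjamini-Hochberg adjusted p was 4.64e-05, with adjusted p = 0.205 with an estimated correlation.

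The glycolysis and hypoxia list was lower in serum-starved cells, with 19 of 21 genes that fell, 0 that rose and 2 that did not pass (median log2 fold change -1.64). Hk2, which traps glucose in the cell, fell 7.61-fold, Tpi1 5.44-fold, Pgk1 (gene ID 24644) 5.38-fold and Ldha, the lactate dehydrogenase subunit, 5.18-fold. Gapdh, often used as a reference gene, fell 3.31-fold, from 5800 ± 279 to 1750 ± 74.2 (limma, Benjamini-Hochberg adjusted p = 1.04e-06), and the glucose transporter gene Slc2a1 fell 4.63-fold. Camera gave a Benjamini-Hochberg adjusted p = 5.1e-12 for the list, and adjusted p = 0.205 with an estimated correlation. Nuclear-encoded respiratory chain genes moved less: 14 of 22 fell, 1 rose and 7 did not pass, with a median of -0.25. Cox5a fell 1.67-fold, Cycs 1.55-fold, Atp5f1b 1.52-fold and Ndufb3 1.48-fold. This list had a camera Benjamini-Hochberg adjusted p = 0.00968, and adjusted p = 0.56 with an estimated correlation. After quantile normalization its median was -0.115 and its adjusted p = 0.133, over alternatives that ranged from 0.0021 to 0.133. In the NRF2 and iron handling list 11 of 21 genes fell, 6 rose and 4 did not pass. Hmox1, the inducible heme oxygenase, fell 4.08-fold, Gclc 2.69-fold, the transferrin receptor gene Tfrc 2.48-fold and Prdx1 1.99-fold (camera, Benjamini-Hochberg adjusted p = 0.0725). That adjusted p was 0.0399 without control replicate 1 and 0.0434 without control replicate 3, within a range of 0.0399 to 0.148. The number of its genes that rose was 2 without control replicate 1 and 3 without control replicate 2 or serum-starved replicate 2. After quantile normalization 4 respiratory chain genes rose.

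**Figure D2:**
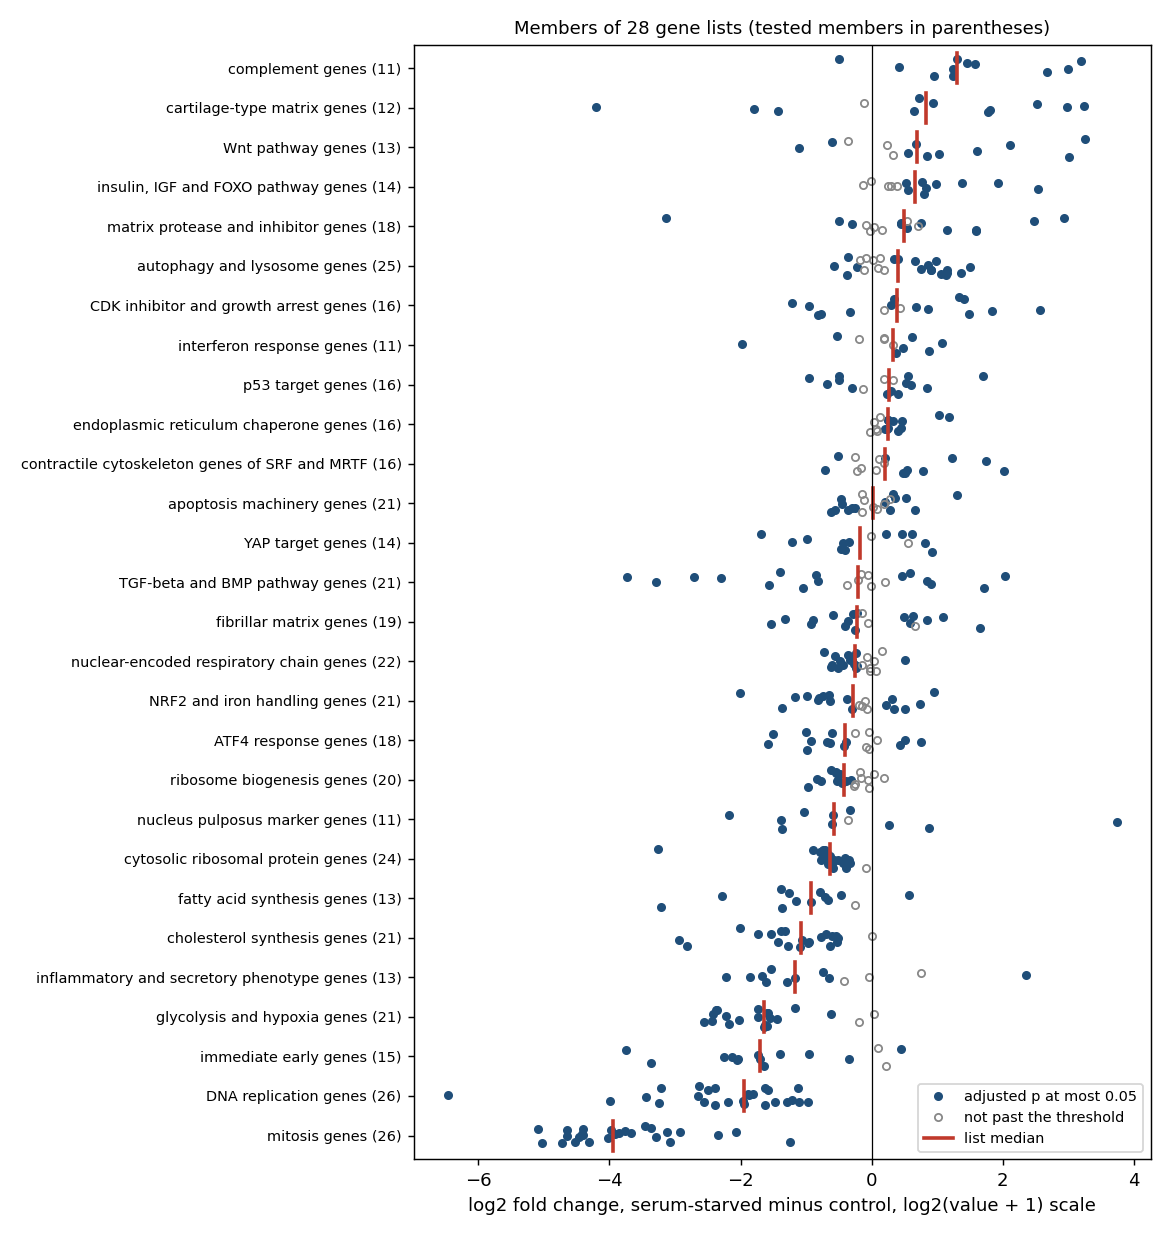
Log2 fold change (serum-starved minus control) of each tested member of 28 gene lists fixed before the data were examined, ordered by list median (red bar), with filled points at an adjusted p of at most 0.05. The medians run from 1.30 in complement genes to -3.94 in mitosis genes, and after quantile normalization the median of fibrillar matrix genes changes sign to 0.007.

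Of 11 tested nucleus pulposus marker genes, 7 fell, 3 rose and 1 did not pass. Slc2a1 fell from 142 ± 5.08 to 30.7 ± 3.10, Cd44, a hyaluronan receptor, fell 2.59-fold from 245 ± 17.6, and Car12, a membrane carbonic anhydrase, fell from 1.76 ± 0.431 to 0.05 ± 0.0361. Car3, another carbonic anhydrase, rose 25.4-fold, from 1.03 ± 0.219 to 26.1 ± 0.852. The list's median was -0.58 (camera, Benjamini-Hochberg adjusted p = 0.105), and -0.387 without control replicate 2. In the cartilage-type matrix list 8 of 12 tested genes rose, 3 fell and 1 did not pass, while 10 of the 22 matched genes were below the filter and not tested. Against the fall of Acan, the proteoglycan genes Dcn (decorin) and Fmod (fibromodulin) rose 8.997-fold and 6.03-fold, to 240 ± 41.6 and 64.3 ± 1.93, and Cilp rose 17.6-fold to 13.4 ± 4.79. Control replicate 3 held Dcn at 44.3 and Acan at 47.2, against 19.1 and 16.5 for Dcn and 82.6 and 103 for Acan in the other controls. Without that library, a choice made after seeing the data, the counts were again 8 and 3. The list's median was 0.83 with a camera Benjamini-Hochberg adjusted p = 0.156, and with the filter at 5 its median was 1.78 and its adjusted p = 0.0395, but with no filter its median was 0.068 and its adjusted p = 0.213, over alternatives that ranged from 0.0395 to 0.225.

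Fibrillar matrix genes went both ways: 10 of 19 fell, 6 rose and 3 did not pass. Postn (periostin) rose 3.39-fold and Lox, the collagen cross-linking lysyl oxidase, 2.12-fold to 1304 ± 61.7, while P4ha1, a prolyl hydroxylase subunit, fell 2.93-fold and Col6a1 2.51-fold. With a median of -0.22, a difference of the list from the other genes was not shown (camera, Benjamini-Hochberg adjusted p = 0.34). The median became 0.007 after quantile normalization, when 6 genes fell. Of 18 matrix protease and inhibitor genes 9 rose, 3 fell and 6 did not pass. Mmp2 (gelatinase A) rose 5.71-fold to 214 ± 34.8 and the aggrecanase gene Adamts5 3.33-fold, while the urokinase gene Plau fell 9.48-fold. Mmp11 rose 6.96-fold, with 7.78 in control replicate 3 against 0.150 and 3.07 in the other controls. The median was 0.49 and the camera Benjamini-Hochberg adjusted p = 0.0846. That adjusted p was 0.0252 after quantile normalization, 0.0489 with library weights and 0.0202 without serum-starved replicate 2, in a range of 0.0202 to 0.14. Of 16 contractile genes driven by SRF and MRTF, 8 rose, 2 fell and 6 did not pass. Acta2, smooth muscle actin, rose 3.90-fold to 554 ± 32.4, Myl9 3.40-fold, Tpm1 2.34-fold and Tagln 1.70-fold (median 0.20, camera, Benjamini-Hochberg adjusted p = 0.153, median 0.446 after quantile normalization). Among 14 YAP target genes 7 fell, 5 rose and 2 did not pass, or 7 and 6 when adjusted over the list alone. F3 (tissue factor) fell 3.22-fold, Nt5e 3.06-fold and Cyr61 1.98-fold, and Ajuba rose 1.94-fold (camera, Benjamini-Hochberg adjusted p = 0.497). Without serum-starved replicate 2 or control replicate 1, 3 YAP targets rose, and without serum-starved replicate 1, 4 contractile genes fell.

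Tested inflammatory and secretory phenotype genes were mostly lower, with 9 of 13 that fell, 1 that rose and 3 that did not pass, or 10 that fell when adjusted over the list alone. Of the 23 matched genes, 10 were below the filter and not tested. Ptgs2, the inducible cyclooxygenase, fell 4.71-fold, from 162 ± 11.1 to 34.5 ± 8.15, and Csf1 3.21-fold. Cxcl10 fell to 1.44, 0.19 and 0.06 in serum-starved replicates 1, 2 and 3, from 3.91, 3.2 and 5.99 in the controls. Cxcl6 rose 14.7-fold, from 0.447 ± 0.336 to 6.58 ± 2.52. The median was -1.17 (camera, Benjamini-Hochberg adjusted p = 0.0159, and adjusted p = 0.417 with an estimated correlation). Without control replicate 3, chosen after seeing the data, 2 genes rose and 7 fell, and 0 rose without serum-starved replicate 2 or 3. With no filter the median was -0.715. Complement genes moved up: 10 of 11 rose and 1 fell, with a median of 1.30. The protease gene C1s rose 6.16-fold to 342 ± 41.6 and C2 3.30-fold. C3 rose from 9.45 ± 10.9 to 63.2 ± 34.4, and control replicate 3 held C3 at 22.1 and C1s at 83.9, against 3.10 and 3.17 for C3 and 38.5 and 44.1 for C1s in the other controls. Camera gave complement genes a Benjamini-Hochberg adjusted p = 0.00123, and adjusted p = 0.365 with an estimated correlation, and 10 again rose without control replicate 3. Without serum-starved replicate 1 or 2, when fewer genes reached the filter, 6 of 8 tested complement genes rose, and 0 fell without serum-starved replicate 2 or 3 or control replicate 1 or 2. In the interferon response list 5 of 11 tested genes rose, 2 fell and 4 did not pass, or 6 and 2 when adjusted over the list alone, and 10 matched genes were below the filter. Gbp2 rose 2.30-fold, Ifit2 1.92-fold and Ifi44 1.67-fold, and Usp18, which restrains interferon signalling, fell 4.73-fold (camera, Benjamini-Hochberg adjusted p = 0.244).

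Cytosolic ribosomal protein genes fell in 23 of 24 cases and 1 did not pass, with a median log2 fold change of -0.64. Rpl4 fell 1.85-fold, from 895 ± 32.5 to 483 ± 46.9, Rps2 1.73-fold and Rpl13 1.70-fold. Rps20 fell from 102 ± 48.8 to 8.97 ± 1.84, but this value is uncertain, since a copy that the reference table names as its pseudogene (LOC100362149) held most of the signal, and the sum of both was 2003 ± 47.6 in control and 1206 ± 83.3 in serum-starved cells, 1.66-fold lower. The camera Benjamini-Hochberg adjusted p was 1.14e-07, with adjusted p = 0.408 with an estimated correlation. After quantile normalization the median was -0.302, 18 genes fell, and Rpl10, named after its values were seen, which did not pass on the deposited scale (log2 fold change -0.08 ± 0.079), rose by 0.29 ± 0.058. Ribosome biogenesis genes fell in 12 of 20 cases, 0 rose and 8 did not pass. Nop56 fell 2-fold, Nop58 1.82-fold, Fbl (fibrillarin) 1.74-fold and Gar1 1.63-fold (median -0.42, camera, Benjamini-Hochberg adjusted p = 0.00144, and adjusted p = 0.476 with an estimated correlation).

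Autophagy and lysosome genes rose in 14 of 25 cases, 4 fell and 7 did not pass, or 15 and 4 when adjusted over the list alone. The cathepsin genes Ctsb and Ctsd rose 2.83-fold to 2035 ± 153 and 2.22-fold to 506 ± 24.2, and the cholesterol carrier gene Npc2 rose 2.58-fold. The median was 0.40 (camera, Benjamini-Hochberg adjusted p = 0.0041, and adjusted p = 0.205 with an estimated correlation), and 2 genes fell after quantile normalization. Endoplasmic reticulum chaperone genes rose in 11 of 16 cases, 0 fell and 5 did not pass. Herpud1 rose 2.31-fold, Dnajb9 2.11-fold, Calr 1.38-fold and Hspa5 1.37-fold (median 0.25, camera, Benjamini-Hochberg adjusted p = 0.0041, and adjusted p = 0.365 with an estimated correlation). The median was 0.403 after quantile normalization. The ATF4 response list, genes of amino acid supply and stress, had 10 of 18 members that fell, 3 that rose and 5 that did not pass. Slc7a5, an amino acid transporter, fell 3.13-fold, the serine pathway genes Psat1 and Shmt2 3.04-fold and 2.04-fold, and Ddit4 2.09-fold. Its median was -0.41 (camera, Benjamini-Hochberg adjusted p = 0.0268, and adjusted p = 0.56 with an estimated correlation). Without control replicate 2 the adjusted p was 0.0706, in a range of 0.00191 to 0.0706.

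In the insulin, IGF and FOXO pathway list 9 of 14 genes rose, 0 fell and 5 did not pass, or 11 rose when adjusted over the list alone. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose 8.54-fold, from 1.66 ± 0.613 to 14.2 ± 0.422. Pik3ip1, an inhibitor of PI3 kinase, rose 5.95-fold, Fbxo32 (atrogin-1) 3.30-fold and Irs2 2.18-fold. The median was 0.66 (camera, Benjamini-Hochberg adjusted p = 0.00198, and adjusted p = 0.205 with an estimated correlation) and 0.39 with no filter. Of 21 TGF-beta and BMP pathway genes 9 fell, 6 rose and 6 did not pass, or 10 and 7 when adjusted over the list alone. The BMP-induced genes Id1, Id3 and Id2 fell 14.0-fold, 9.16-fold and 6.67-fold, with Id1 at 108 ± 4.74 in control and 7.73 ± 3.82 in serum-starved cells. The list's median of -0.20 had a camera Benjamini-Hochberg adjusted p = 0.189, which was 0.0285 without serum-starved replicate 2 (median -0.341), in a range of 0.0285 to 0.281, and the median was -0.302 without serum-starved replicate 1. Of 13 Wnt pathway genes 8 rose, 2 fell and 3 did not pass, or 9 and 2 when adjusted over the list alone. The largest rises were in genes whose products restrain Wnt signalling: Apcdd1 rose 12.1-fold, Sfrp2 10.98-fold, Wif1 7.02-fold and Sfrp4 3.75-fold. The median was 0.69 (camera, Benjamini-Hochberg adjusted p = 0.016, and adjusted p = 0.355 with an estimated correlation). With no filter on low values the Wnt median was 0.154 and its camera adjusted p = 0.291, in a range of 0.00476 to 0.291. In that setting 8 of 20 Wnt genes rose and 5 fell, counts added after seeing the data, and 1 Wnt gene fell without control replicate 1 or 2. For every list with no separate count given, the numbers adjusted over the list alone were the same as those over all genes.

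Among macrophage markers 3 were tested: Cd14 fell 2.91-fold, and Laptm5 and Cd68 rose to 1.72 ± 0.0854 and 3.38 ± 0.600. The only tested endothelial marker, Egfl7, fell 1.53-fold. Of 7 annulus and tendon markers 3 rose, 2 fell and 2 did not pass, or 4 and 2 when adjusted over the list alone. The tendon transcription factor gene Mkx rose 2.96-fold and Thbs4 fell 2.18-fold (camera, Benjamini-Hochberg adjusted p = 0.675). All 3 tested osteoblast and hypertrophic markers fell: Ibsp 11.1-fold, Spp1 (osteopontin) 2.62-fold, from 3552 ± 379 to 1358 ± 343, and Runx2 1.31-fold. Des (desmin), on the skeletal muscle and pericyte lists, fell 9.73-fold, from 125 ± 12.1 to 12.9 ± 2.37, and Acta1 rose from 0.0633 ± 0.0709 to 1.37 ± 0.283. Of 3 tested skeletal muscle markers 1 rose, 1 fell and 1 did not pass, with a median of 0.10 and a mean of -0.65. Pericyte and smooth muscle markers split into 3 that rose, 3 that fell and 3 that did not pass of 9, with Cspg4 2.88-fold and Mcam 1.82-fold lower and Pdgfrb 1.88-fold higher. Their median was 0.30 and their mean -0.27, and camera gave the direction as down (Benjamini-Hochberg adjusted p = 0.862). Of 3 Schwann and glial markers 2 rose and 1 did not pass, and S100b, among those that rose, was 3.55-fold higher at 114 ± 4.64. The only tested adipocyte marker, Cebpa, rose to 1.81 ± 0.1002, and 0 red cell markers had values high enough to test. Without any single serum-starved library fewer of these low genes reached the filter, so 1 macrophage, 1 Schwann and glial and 0 skeletal muscle markers rose and 0 adipocyte markers were tested.

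Among the most abundant transcripts that rose were Fn1 (fibronectin), at 5290 ± 956 against 3391 ± 18.6 in control cells, Thbs1 (2.90-fold), Col1a1 (1.499-fold) and Sparc (1.41-fold). Fth1, the ferritin heavy chain gene, rose 1.23-fold (limma, Benjamini-Hochberg adjusted p = 0.0236). That call was lost with no filter (0.113), without control replicate 1 (0.0849) or 2 (0.0854) and without serum-starved replicate 2 (0.051), in a range of 0.0013 to 0.113. The most abundant that fell, besides Gapdh, were Ftl1 (1.56-fold), Vim (vimentin, 1.41-fold), Lgals1 (2.09-fold) and S100a6 (2.18-fold). After quantile normalization, which raised abundant genes of serum-starved libraries, the log2 fold change of Vim was -0.142 (limma, Benjamini-Hochberg adjusted p = 0.205, in a range of 0.00094 to 0.205) and that of Ftl1 was -0.299.

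Within a group, libraries correlated across genes at r = 0.994 to 0.9964, and between groups at 0.9519 to 0.963, where genes are not independent replicates. The first principal component held 88.5% of the variance and separated the groups. Groups did not overlap in 7837 tested genes (68.2%, where chance gives 10%). In all, 16 of 30 lists were called by camera and 0 with an estimated correlation (5 at an unadjusted p under 0.05), whereas fry, which does not compare a list with other genes, gave 28 of the 30 lists an adjusted p of at most 0.05, including 12 of the 14 that camera did not call. Anln and Aspn have near-copies in the files (Anlnl1 and Aspnl1) that moved the same way, so their levels are uncertain. At a pseudocount of 0.1 the number of genes that rose at least 2-fold was 779 instead of 479, and the number that fell at least 2-fold was 980 instead of 825.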

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

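No alternative in this part was chosen after seeing the data except the counts of list members without single libraries and after quantile normalization. The replicate number served as a block in 1 alternative, although it did not pair the libraries: same-numbered libraries deviated from their group means with correlations of 0.037, -0.162 and 0.101, and not every library correlated best with its own number. With the replicate block 6801 genes changed, 1305 at least 2-fold, and among named genes 1 call was lost, that of Fth1 (limma, Benjamini-Hochberg adjusted p = 0.0833), while the matrix protease list passed (camera adjusted p = 0.0424). Over the 15 alternatives the number of changed genes ran from 5533, with the filter at 5, to 7810, with library weights, and 0 genes called in both fits changed sign. Leaving out each library in turn gave 5899 to 6683 changed genes, 1082 to 1270 at least 2-fold, 377 to 526 of these higher and 626 to 856 lower. Fewer genes reach the filter when a library is left out (11228 to 11238), and genes silent in starved cells lose their place when a control is removed, so the mitosis list then had 21 tested genes without control replicate 3. At a pseudocount of 0.1, 779 genes rose and 980 fell at least 2-fold, since a smaller pseudocount gives larger fold changes to low genes. With an estimated correlation 0 of the 16 list calls were left, and without it the number of called lists ran from 15 to 18. The estimated correlation of the autophagy and lysosome list was 0.00968, below the preset 0.01. Its camera adjusted p still went from 0.0041 to 0.205, so the loss of calls cannot be read as an effect of correlation between genes alone. The direction of the apoptosis list, called under no alternative, turned with the filter at 5 (median 0.084) and without serum-starved replicate 1 (0.038) or 3 (0.021), and that of the pericyte list without serum-starved replicate 2 (0.331). With single libraries left out these medians ran from -0.039 to 0.042 and from 0.129 to 0.445, and the cause was not tested. Of the values of named genes, 2227 were on the same side of the threshold with the same direction and 6 lost their call, all in Fth1 or Vim. Depth is unknown, so how far it limits calls among low genes could not be read from the files.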

Other observations

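In this part, the family of small leucine-rich proteoglycans, the genes of fatty acid use named next to it, the genes that prompted the question on LXR, Lcn2, the genes near 0 in controls, the single members named from each added list, the 3 tests on control replicate 3, the test of scaling as the whole cause and the other scalings of the added lists were chosen only after the result was seen. Small leucine-rich proteoglycans, which bind collagen fibrils, were mostly higher: of 11 tested members 10 rose, 0 fell and 1, Podnl1, did not pass (4.55 ± 0.49 against 3.63 ± 0.62). Aspn, Ogn, Dcn and Fmod, which prompted the choice of this family, are among the 10, so the count is no independent support for a shared rise. Omd (osteomodulin) was at 10.2 ± 2.74 in serum-starved and 0.02 ± 0.02 in control cells, Ecm2 at 7.09 ± 0.33 against 0.39 ± 0.04, Lum (lumican) at 10.6 ± 2.53 against 2.46 ± 1.24 and Optc at 2.82 ± 0.42 against 0.55 ± 0.11. The abundant members moved less, with Bgn (biglycan) 1.91-fold and Prelp 1.29-fold higher. Genes of fatty acid use also rose. Cpt1a, which lets long-chain fatty acids into mitochondria, was 12.5-fold higher at 59.7 ± 3.03, Hadha 4.25-fold at 165 ± 2.80, Ech1 4.804-fold at 167 ± 16.5 and the carnitine transporter gene Slc22a5 7.38-fold at 13.3 ± 0.97.

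A hypothesis from these genes was that fatty acid oxidation genes rose more widely. Among 17 tested genes of the pathway whose values had not been looked at, 11 rose, 0 fell and 6 did not pass, with a median log2 fold change of 0.49, where a median of at most 0.1 would have counted against it. Under the other scalings the median was 0.465 and 0.554. Acaa2 rose by 1.35 ± 0.108 (SE), Decr1 by 0.87 ± 0.076 and Acadm by 0.67 ± 0.065, while Etfa stood at -0.14 ± 0.089 and Echs1 at -0.11 ± 0.125. The values are consistent with a shared rise of the pathway in cells without serum. Whether the cells burned more fat was not measured.

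The cholesterol synthesis genes fell in medium without serum, although serum is the source of lipoprotein cholesterol. Another scaling of the libraries argues against a normalization effect, since the median was -1.005 under the scaling that left it closest to 0. An effect of abundance is argued against as well, because 0% of 10000 random lists matched on mean expression had a median as low, their central range being -0.241 to 0.208. A candidate explanation is an excess of sterol in the cells, which would also raise targets of the sterol sensor LXR, and Apoe (log2 fold change 3.84), Abca1 (1.86) and Smpdl3a (2.19) prompted it, while Srebf1, an LXR target on the fatty acid synthesis list, fell (-1.255). Among 5 tested LXR targets not looked at before, 2 rose, 2 fell and 1 did not pass. Their median was -0.183 (standard error 0.674), with values from -1.98 (Arl4c) to 1.23 (Nr1h3). A median at or below 0 had been set beforehand to count against sterol excess, and this bound was met. However, the median's distance below 0 was smaller than its standard error, so these 5 genes do not decide the question. Sterol excess and a direct effect of growth factor loss on the synthesis genes both stay open.

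Ribosomal protein genes fell together, and scaling may account for part of it. Scaling as the whole cause is argued against, since the median of -0.64 on the deposited scale was -0.302 after quantile normalization (SD between libraries 0.032), where 18 of 24 genes fell, 1 rose and the list was called (camera, Benjamini-Hochberg adjusted p = 7.47e-05, and adjusted p = 0.35 with an estimated correlation), and -0.661 under median-ratio scaling, where 23 fell. How much of the fall scaling accounts for stays open, because -0.302 lay between the bounds set beforehand (-0.2 and -0.4) and no count or spike-in was used here to fix the scale. Against abundance alone, the median lay at percentile 0.04 of random lists matched on mean expression, whose central range was -0.486 to 0.051. Those lists drew genes independently, while the ribosomal list had an estimated correlation of 0.693 between its genes. The percentile therefore overstates the evidence, and how much of the fall abundance accounts for stays open. Of 12 other transcripts with a 5' TOP motif, the sequence through which growth signals act on ribosomal protein mRNAs, 8 fell and 0 rose both on the deposited scale (median -0.412, led by Hnrnpa1 at -1.52 ± 0.072) and under median-ratio scaling (-0.438), but 5 fell and 2 rose after quantile normalization (-0.112), so whether the class shared a fall stays open.

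Control replicate 3 lay closer to the serum-starved libraries in genes that rose, for example in C3 (22.1), Lcn2 (205 against 27.3 and 37.9 in the other controls) and Angptl4 (5.28). Starved RNA mixed into that library is argued against by Aspn, the only gene below 1 in the other controls and above 20 in every starved library, whose share of the starved level was -0.0001, and in 73 genes under a wider limit the median share was 0.0173 (quartiles -0.0075 and 0.1141). A scaling factor of the whole library is argued against by a median log2 ratio of -0.002 over all tested genes. A partial shift of the whole response stays open: with each control measured in the genes called at least 2-fold without it, control replicate 3 had gone a median of 0.055 of the way to the starved level in 526 genes that rose, against 0.014 (492 genes) and -0.032 (456 genes) for controls 2 and 1, while in genes that fell the medians were 0.061, 0.085 and -0.099 for controls 3, 2 and 1. No biological explanation was tested, since the labels name none within the control group.

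Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many as 7024 changed genes, and the highest of the others gave 0 with limma (196 at an unadjusted p under 0.05, against 7547). With 10 splits the share cannot fall under 0.05. Every split but the real one also put serum-starved and control libraries together in both groups, so the treatment difference widened the spread within them. Their low counts therefore do not measure chance. Genes below 0.2 in every control and at least 5 in every starved library numbered 5: Omd, Hist2h2aa3, Hmgn1, Hprt1 and LOC102552055. Hmgn1 was listed at 0 in all 3 controls and at 15.3, 5.03 and 17.6 in starved libraries, and Hprt1 at 0.15, 0 and 0 against 12.4, 10.9 and 8.59.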
